A study of Mus musculus with 3 samples.

How the data were processed

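Total RNA-seq libraries of 3 biological replicates were used, each made after ribosomal RNA depletion from 1 µg of RNA of the cytosolic fraction of bone marrow-derived macrophages 10 minutes after 100 ng/ml Lipid A, per the labels. All 3 carry 1 donor identifier in the labels, sex was not collected, and the labels do not say whether the replicates came from separate animals or cultures, so the tests measure the spread between these samples only. Strandedness and read layout are not given in the sources used here.

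Each library came with 1 gene table and 2 transcript tables. The gene table and the first transcript table give expected counts and TPM that the authors derived from alignments to the transcriptome of assembly mm10 with annotation M21, per the file headers and the text files beside them, and their column layout is the one RSEM writes. The second transcript table gives estimated counts and TPM that the authors derived from the reads directly with the same assembly and annotation, and its column layout is the one kallisto writes. The aligner, the quantifiers and their versions are not given in the sources used here. The deposited TPM divides counts by effective transcript length and scales each library to the same total, so a few very short, abundant RNAs set the scale of all other genes. The first transcript table also gives the TPM of each transcript as a percentage of its gene's TPM, computed by the authors. Shares of transcripts given here were computed anew from the deposited TPM. The deposited posterior standard deviation of each count was used in 1 alternative below.

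Each gene table has 81881 entries: 55536 Ensembl genes, 96 ERCC spike-in controls, 1 phiX174 genome and 26248 entries named by a bare number. All 55536 Ensembl identifiers matched the M21 annotation, from which symbols, biotypes and coordinates were taken. The phiX174 entry held 0.449%, 0.203% and 0.141% of the counts in replicates 1, 2 and 3, ERCC controls had none, and the numbered entries held 3, 1 and 0 counts. These entries were left out of library sizes and tests but remain in the deposited TPM scale. Gene counts then totalled 33825547 in replicate 1, 54667365 in replicate 2 and 43176007 in replicate 3. The second transcript table totalled 37499131 in replicate 1, 66949618 in replicate 2 and 55268656 in replicate 3.

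Levels were compared on the log2(TPM + 1) scale, which understates differences between low genes, and list medians were averaged over libraries. The 27 gene lists and the rule for named genes were fixed before the data were examined. So were the tests and the alternatives, except those described below as chosen, added or changed after values were seen. Of 384 list members, 382 matched a symbol (Irg1 and Rn45s did not). The rule names up to 6 of the highest and up to 4 of the lowest members of each list, a fixed set of TLR4 pathway and response genes, the 10 genes with the highest TPM, the 10 with the largest SD of log2(TPM + 1) at a mean of 10 TPM or more, and the 10 with the largest ratio in each direction between both transcript quantifications. Genes named outside it, Rps20, Rps16, Tap2, Irf3, Sod2, Ier3, Gm28661, Gm28437, Mpo, Olfr111 and Olfr56, were chosen after their values were seen. Some genes that the rule names are not reported.

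Differences between lists in the same library were tested with a two-sided exact sign-flip permutation test, whose smallest p for 3 libraries is 0.25. Differences between libraries were tested per gene by a chi-square test of rounded estimated counts against TMM effective library sizes, for genes with a summed count of 30 or more, with Benjamini-Hochberg adjustment at 0.05, and sized by the common dispersion of an intercept-only edgeR model. A list's spread or retained intron share was compared with 10000 random lists of the same size in 20 bins of expression. The 2 transcript quantifications were compared as log2 ratios with 0.1 added to both, for genes at 5 TPM or more in either. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.

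The procedures were tested on simulated data. With 100 genes changed 1.5-fold and 100 changed 2-fold in 1 library among 13494, the counting test recovered 79% and 89% and called 0.06% of the unchanged genes. The list test over 9944 genes called 99% of lists of 20 genes with a doubled SD and 5% of unchanged lists. The simulated genes varied independently with a common SD, so these rates may not hold for lists whose genes move together. For the 3 libraries simulated with coefficients of variation of 5%, 10% and 20% over 13494 genes, edgeR returned 5%, 10% and 20%.

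Alternatives varied the pseudocount, filters on low values, the scaling, the quantification, the list summary and the libraries used. Reads shared between near-identical copies, such as 7SL, U3 and mitochondrial genes with nuclear copies, make the level of a single copy uncertain. No comparison between conditions was made because the series holds 1 condition.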

Results

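Total RNA was sequenced from the cytosolic fraction of macrophages grown from the bone marrow of C57BL/6J mice and stimulated for 10 minutes with 100 ng/ml Lipid A, the membrane-anchored part of bacterial lipopolysaccharide that the receptor TLR4 recognises. The series held 1 group of 3 biological replicates. It held no untreated cells, so every value below is a level 10 minutes after stimulation and not an induction. Estimated counts totalled 33978273 in replicate 1, 54778530 in replicate 2 and 43237143 in replicate 3. At these depths, 3 counts on a transcript of 1 kb corresponded to 0.045, 0.029 and 0.040 TPM, a measure of transcript share that allows for length. That is the limit that a count of 0 allows, and it covers counting error only. Genes at 1 TPM or more numbered 9847, 9828 and 10046, and 9602 genes, of which 9164 were protein-coding, reached it in every library. All coordinates are those of mm10 with the GENCODE M21 annotation.

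The composition of the cytosolic RNA was examined first. A few short noncoding RNAs held most of the TPM: the 7SL RNA of the signal recognition particle, which targets secreted proteins to the endoplasmic reticulum, took 58.7% ± 1.20 (SD, n = 3), the 7SK RNA (Rn7sk) 7.10% ± 1.30, the RNase P RNA (Rpph1) 4.82% ± 0.633 and the RNase MRP RNA, summed over both Rmrp entries, 2.56% ± 0.319. Protein-coding genes of the nuclear genome took 24.3% ± 1.18 of the TPM. Because TPM divides by effective transcript length, which is small for short RNAs, the same genes took very different shares of the estimated counts. These were 86.7% ± 1.43 for protein-coding genes and 8.72% ± 1.32 for 7SL. In the second quantification, 7SL took 31.6%, 18.5% and 14.2% of the TPM in replicates 1, 2 and 3. The TPM shares of such short RNAs therefore depend on the quantification and are uncertain. The 7SL reads were split between near-identical copies, Rn7s2 (ENSMUSG00000099250.1, chromosome 12, 69361182 to 69361481; 294724 ± 6414 TPM) and Rn7s1 (ENSMUSG00000099021.1, chromosome 12, 69159295 to 69159594; 292351 ± 5636 TPM), so the level of either copy alone is uncertain. The other genes among the 10 highest were protein-coding: Ftl1 at 7725 ± 189 TPM and Fth1 at 6732 ± 40.8 TPM, the light and heavy chains of the iron store ferritin, Lyz2 at 4969.7 ± 427 TPM, which encodes lysozyme, and Psap at 4815 ± 274 TPM, the precursor of the saposins. Pseudogenes took 0.661% ± 0.0494, long noncoding RNA biotypes 1.03% ± 0.297, small nuclear, nucleolar and Cajal body RNAs 0.960% ± 0.174 and mitochondrial messenger RNAs 0.591% ± 0.0558. The ribosomal RNA entries measured were low, with mt-Rnr1 at 7.47 ± 1.85 TPM, mt-Rnr2 at 4.03 ± 1.14 TPM and n-R5s136 without a count. Rn45s, the precursor of the large cytosolic ribosomal RNAs, did not match a symbol, so the lists held no measure of what remained of those RNAs.

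The next comparison asked which cell types the libraries held. All 20 macrophage markers were at 1 TPM or more in every library, with a list median of 232 ± 15.2 TPM (SD, n = 3). Lyz2, Apoe (1953 ± 384 TPM), Tyrobp (826 ± 65.3 TPM), the complement gene C1qb (773 ± 71.5 TPM), Mpeg1 (728 ± 52.1 TPM) and Cd68 (716 ± 62.1 TPM) were the highest of the list. Among the lowest were the transcription factor Cebpb (8.72 ± 2.45 TPM), Itgam (29.1 ± 9.90 TPM) and Mertk (33.6 ± 2.02 TPM). Most markers of other lineages were below 1 TPM. List medians were 0.418 ± 0.0729 TPM for neutrophils and their precursors, 0.132 ± 0.0520 TPM for dendritic cells, 0.0133 ± 0.0153 TPM for T and NK cells, 0.03 ± 0.0346 TPM for B cells, 0.0383 ± 0.0202 TPM for mast cells and basophils, 0.253 ± 0.203 TPM for osteoclasts, 0.00667 ± 0.00577 TPM for stromal cells and 0 for erythroid cells. The neutrophil alarmins S100a9 (17.6 ± 4.01 TPM) and S100a8 (11.8 ± 2.86 TPM), the collagenase Mmp8 (6.02 ± 0.936 TPM), the immunoglobulin gene Ighm (5.17 ± 0.761 TPM) and the proton pump subunit Atp6v0d2 (57.9 ± 15.3 TPM) stood above the rest of their lists. Globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and the granulocyte marker Ly6g had no count. The T cell gene Lck reached 0.1 ± 0.0361 TPM, the mast cell receptor Kit 0.507 ± 0.0681 TPM, the dendritic cell factor Batf3 1.53 ± 0.185 TPM and the chemokine Cxcl12, the highest stromal marker, 0.0233 ± 0.0153 TPM.

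On the log2(TPM + 1) scale the macrophage list exceeded the neutrophil list by 7.33 ± 0.14 (SD, n = 3), the osteoclast list by 7.50 ± 0.14, the dendritic list by 7.64 ± 0.16, the mast cell list by 7.76 ± 0.14, the B cell list by 7.77 ± 0.15, the T and NK list by 7.80 ± 0.10, the stromal list by 7.81 ± 0.11 and the erythroid list by 7.82 ± 0.11. Each difference had the same sign in 3 of 3 libraries and was many times the spread between replicates. Their size rests in part on markers near 0: over members with a mean of 1 TPM or more, the difference was 4.59 ± 0.18 for neutrophils, 5.66 ± 0.14 for B cells, 6.29 ± 0.08 for erythroid cells, 6.48 ± 0.05 for dendritic cells and 6.63 ± 0.15 for osteoclasts. The two-sided exact sign-flip permutation test gave p = 0.25 for each, which is the smallest p that 3 libraries allow, so it cannot pass 0.05.

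**Figure D1:**
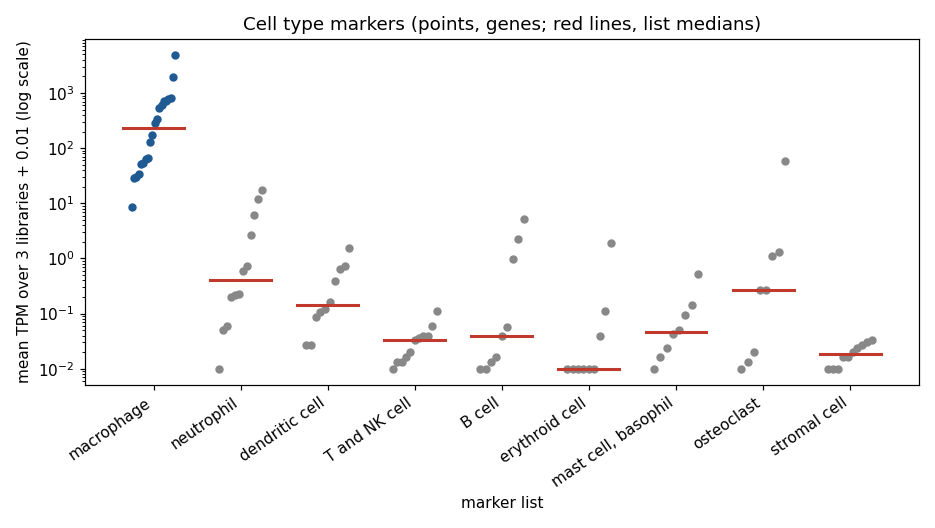
Mean TPM over the 3 libraries plus 0.01, on a log axis, for each marker gene (points) of the 9 cell type lists, with a red line at each list's median. Macrophage markers lie between 8.72 and 4969.7 TPM, and the highest marker of any other list is Atp6v0d2 at 57.9 TPM.

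Genes of the receptor pathway that senses Lipid A were detected, at levels that depend on the TPM scale. Of 23 pathway genes, 22 were at 1 TPM or more in every library, with a list median of 8.34 ± 0.265 TPM (SD, n = 3). After rescaling TPM over protein-coding genes, the list median was 34.4 ± 2.24 TPM. The co-receptor Cd14 was at 51.6 ± 5.49 TPM, the receptor Tlr4 (ENSMUSG00000039005.13, chromosome 4, 66827584 to 66930284) at 30.4 ± 2.44 TPM, its adaptors Myd88 at 18.9 ± 0.461 TPM and Ticam1 at 7.64 ± 0.441 TPM, and Ly96, which encodes the lipid-binding partner MD-2, at 15.9 ± 1.14 TPM. The kinase genes Ikbke and Tbk1 stood at 20.0 ± 2.98 TPM and 16.4 ± 0.302 TPM and Tab2 at 23.1 ± 1.38 TPM. The lowest members were Traf3 (3.56 ± 0.341 TPM), Tab1 (2.82 ± 0.246 TPM), Tirap (2.70 ± 0.157 TPM) and Lbp (0.453 ± 0.166 TPM), the serum lipopolysaccharide-binding protein. All 16 transcription factors downstream of TLR4 were at 1 TPM or more in every library. Interferon pathway factors were among the highest, with Irf7 at 56.5 ± 4.07 TPM, Irf8 at 56.3 ± 2.62 TPM, Irf5 at 33.7 ± 1.91 TPM, Stat2 at 27.5 ± 1.35 TPM and Irf1 at 20.8 ± 3.81 TPM. Rel (6.30 ± 0.261 TPM), Srf (5.41 ± 0.399 TPM), Creb1 (5.35 ± 0.397 TPM) and Elk1 (3.64 ± 0.150 TPM) were lowest. The list median was 14.3 ± 0.540 TPM.

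The labels place the cells 10 minutes after Lipid A, so the levels of genes known to respond at different times were compared within each library. Of 24 immediate early genes, which are transcribed without new protein synthesis, 21 were at 1 TPM or more in every library, with a list median of 10.6 ± 2.73 TPM (SD, n = 3). Atf3 (74.3 ± 7.50 TPM), Zfp36 (48.5 ± 11.3 TPM), which encodes an mRNA-destabilising protein, Klf6 (42.5 ± 2.15 TPM), Jun (39.5 ± 4.54 TPM), Junb (33.9 ± 9.84 TPM) and Plk2 (29.6 ± 4.66 TPM) led the list. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) was at 26.7 ± 10.1 TPM, Ier2 at 13.1 ± 4.43 TPM, Egr1 at 12.3 ± 4.04 TPM and the phosphatase gene Dusp1 at 8.78 ± 1.45 TPM. Dusp5 (1.63 ± 0.431 TPM), Fosb (0.953 ± 0.240 TPM), Maff (0.483 ± 0.0850 TPM) and Plk3 (0.333 ± 0.00577 TPM) were lowest. Among 20 inflammatory genes of the primary response, 17 were at 1 TPM or more in every library and the list median was 6.13 ± 0.601 TPM. The chemokine genes Ccl3 (82.2 ± 2.99 TPM), Ccl4 (56.5 ± 4.23 TPM), Ccl2 (24.2 ± 11.4 TPM) and Ccl7 (20.0 ± 5.57 TPM), the activation marker Cd83 (30.6 ± 4.73 TPM) and the NF-kB inhibitor Nfkbia (16.3 ± 1.36 TPM) were highest. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) stood at 6.92 ± 0.817 TPM, Cxcl2 at 3.08 ± 0.565 TPM and Il1b at 1.97 ± 0.193 TPM. Nfkbid (1.63 ± 0.212 TPM), Tnfsf9 (0.730 ± 0.243 TPM), Cxcl1 (0.480 ± 0.104 TPM) and the cyclooxygenase gene Ptgs2 (0.2 ± 0.0436 TPM) were lowest.

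The list of secondary and interferon-dependent genes held genes at very different levels. Of its 25 members, 10 were below 1 TPM in every library, among them Il12b (0.217 ± 0.0321 TPM), Ifnb1 (0.0433 ± 0.0451 TPM), Nos2 (0.03 ± 0.02 TPM), Il6 (0.0133 ± 0.0153 TPM) and Csf3, which had no count. The interferon-stimulated genes Ifit2 (84.6 ± 17.2 TPM), Ifit3 (76.8 ± 11.9 TPM), Rsad2 (58.6 ± 4.60 TPM) and Isg15 (29.8 ± 2.63 TPM) were detected in every library, and Cxcl10 was at 9.30 ± 4.84 TPM. Ccl5 (12.2, 35.4 and 73.0 TPM in replicates 1, 2 and 3) and the acute phase gene Saa3 (4.24, 22.9 and 75.1 TPM) differed several-fold between replicates. The list median was 2.00 ± 0.466 TPM. On the log2(TPM + 1) scale the immediate early list exceeded it by 1.91 ± 0.38 (SD, n = 3) and the early inflammatory list exceeded it by 1.25 ± 0.15. Both held in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25, the smallest possible). These differences rest on the late genes below 1 TPM: over members with a mean of 1 TPM or more, the immediate early difference was 0.26 ± 0.51 and the early inflammatory difference was -0.32 ± 0.10.

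**Figure D2:**
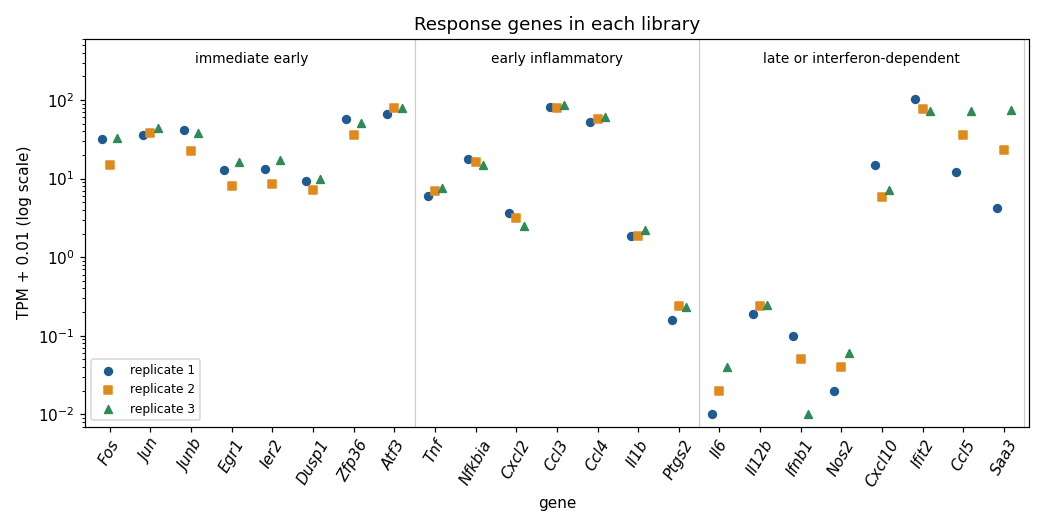
TPM plus 0.01, on a log axis, of selected response genes in each of the 3 libraries (1 point per replicate), grouped as immediate early, early inflammatory and late or interferon-dependent genes. Ccl3 lies between 80.1 and 85.6 TPM, Il6 lies at 0.03 TPM or below, and Fos has its lowest value, 15.1 TPM, in replicate 2.

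Because the RNA was labelled as cytosolic, RNAs known to stay in the nucleus were set against messenger RNAs of the ribosome. All 30 ribosomal protein genes were above 10 TPM in every library, led by Rplp1 (721 ± 28.4 TPM), Rps24 (498 ± 51.9 TPM) and Rpl19 (435 ± 7.58 TPM), with Rpl5 (21.3 ± 0.380 TPM) lowest and a list median of 242 ± 7.07 TPM (SD, n = 3). Of 12 nuclear long noncoding RNAs, 6 were at 1 TPM or more in every library. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), an abundant RNA of nuclear speckles, was at 428 ± 152 TPM, Neat1, the scaffold of paraspeckles, at 39.0 ± 4.60 TPM, Tug1 at 18.1 ± 0.129 TPM and Xist, which coats the inactive X chromosome, at 4.69 ± 3.73 TPM, while Meg3 had no count. The ribosomal protein list exceeded the nuclear long noncoding list by 6.96 ± 0.22 on the log2(TPM + 1) scale, in 3 of 3 libraries (two-sided exact sign-flip permutation test, p = 0.25). Over members with a mean of 1 TPM or more it was 3.16 ± 0.12. Without a nuclear or whole-cell library to compare with, this difference does not measure how well the fractions were separated. Malat1 itself lay above the ribosomal protein median. Small RNAs gave a mixed picture. Of 14 nuclear small RNAs, Rn7sk (71004 ± 12980.0 TPM) and Rpph1 (48163 ± 6335 TPM) were far above the list median of 16.9 ± 4.05 TPM, followed by Scarna10 (121 ± 26.3 TPM), Snora73b (65.0 ± 23.6 TPM), Scarna2 (43.2 ± 5.03 TPM) and Snora73a (42.6 ± 22.3 TPM). Another 4, including Rnu11 and Snord118, had no count. Of the cytosolic small RNAs, the vault RNA Vaultrc5 was at 129 ± 42.4 TPM and the Y RNAs Rny1 and Rny3 had no count. The labels give a size range of 250 to 400, and RNAs shorter than the fragments are measured poorly by such libraries.

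Among 3870 genes at 5 TPM or more that have an annotated retained intron transcript, the median share of a gene's TPM in such transcripts was 1.56% ± 0.637 (SD, n = 3), with 2.27% in replicate 1, 1.35% in replicate 2 and 1.05% in replicate 3. The share exceeded 10% in 576 genes. Ribosomal protein genes had a list median of 0.295% against 0.494% in random lists of like expression, at percentile 4.67 of 10000 such lists. Antigen presentation genes (4.91% against 1.01%, percentile 96.9) and TLR4 pathway genes (4.22% against 1.82%, percentile 96.1) had larger medians, but none of these lists lay outside the central 95% of its matched lists. The second quantification put the order of the latter lists the other way, at 3.06% for antigen presentation and 11.6% for TLR4 pathway genes. Single genes went far beyond their lists, with 90.3% ± 0.120 for Rps20, 85.0% ± 2.83 for Rps16, 76.8% ± 4.30 for the peptide transporter gene Tap2 and 71.9% ± 1.66 for Cd83. All these shares are of TPM assigned to annotated transcripts. Reads over the introns were not examined, so the shares do not show that this part of the RNA kept an intron. The percentiles describe these libraries, since genes are not replicates.

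Replicates were then compared with each other. Across all 55536 genes, Pearson correlations of log2(TPM + 1) were 0.993 between replicates 1 and 2, 0.992 between 1 and 3 and 0.996 between 2 and 3, computed across genes, which are not independent. Estimated counts differed beyond counting error in 6765 of 13494 genes tested (50.1%; chi-square test, Benjamini-Hochberg threshold 0.05), a count that grows with depth wherever replicates vary at all. The common coefficient of variation between replicates in edgeR was 14.5%. Leaving out replicate 1 reduced the differing genes to 3514 of 12785. Of 9944 genes with a mean of 1 TPM or more, 357 (3.59%) had a highest library at least 2 times the lowest.

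Some gene groups differed between replicates more than genes of like expression. All 18 cell division genes were highest in replicate 3, with Top2a, which untangles DNA, at 3.89, 4.43 and 13.5 TPM in replicates 1, 2 and 3, the proliferation marker Mki67 at 2.91, 3.09 and 9.62 TPM, the mitotic kinase gene Cdk1 at 5.29, 4.70 and 13.1 TPM and Pcna, the replication clamp, at 54.2, 64.9 and 86.5 TPM. All 19 replication-dependent histone genes were also highest in replicate 3, among them Hist1h4h at 54.9, 53.0 and 93.9 TPM and Hist2h2ac at 17.3, 24.4 and 44.1 TPM. The 6 detected nuclear long noncoding RNAs were all highest in replicate 1, with Malat1 at 597, 383 and 304 TPM, Xist at 8.97, 2.09 and 3.02 TPM and Gm26917 at 260.3, 37.5 and 43.8 TPM. The smallest rise among the 6 was only 0.22 TPM, so not all of them differed by much. Of 21 detected immediate early genes, 12 were lowest in replicate 2, among them Fos (32.0, 15.1 and 33.0 TPM) and Junb (41.0, 22.6 and 38.0 TPM). On the deposited TPM, ribosomal protein genes had the smallest median SD of the 16 lists, 0.06 on the log2(TPM + 1) scale.

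The test set each list's median SD of log2(TPM + 1) against 10000 random lists matched on expression, two-sided, with adjustment over 16 lists. Medians were 0.65 for cell division, 0.47 for histone and 0.23 for immediate early genes, against 0.11, 0.10 and 0.10 in matched lists, each with an adjusted permutation p of 0.000533, from the smallest raw p the resampling can give. Late inflammatory (0.24) and nuclear small RNA genes (0.30) had the same adjusted permutation p, and it was 0.0016 for nuclear long noncoding RNAs, 0.000914 for phagocytic receptors, 0.00391 for mitochondrial messenger RNAs and 0.0378 for early inflammatory genes. Ribosomal protein genes spread less than matched genes on the deposited TPM (difference of -0.049, adjusted permutation p = 0.000533). That result depends on the scaling, since the difference was 0.014 on TMM-normalised counts (adjusted permutation p = 0.247) and -0.013 on TPM rescaled over protein-coding genes (adjusted permutation p = 0.413), a step chosen after seeing the data. Mitochondrial messenger RNAs had an adjusted permutation p of 0.0579 after that rescaling. The excess of nuclear small RNAs over matched genes was 0.199 on the deposited TPM. On TMM-normalised counts it was 0.098 (adjusted permutation p = 0.0458). Macrophage markers (0.184), TLR4 pathway genes (0.495), transcription factors (0.173), lysosomal genes (0.495), antigen presentation genes (0.703) and heat shock genes (0.495) did not pass 0.05 by the adjusted permutation p given for each. Genes are not independent replicates, so these p-values describe the lists within these libraries. The median of all genes with a mean of 1 TPM or more lay 0.07 above the 3-library mean in replicate 3, 0.03 below it in replicate 1 and 0.04 below it in replicate 2. The excess spread of cell division and histone genes rests on replicate 3, without which it was 0.007 (adjusted permutation p = 0.85) and 0.006 (adjusted permutation p = 0.85). Without replicate 1, the adjusted permutation p was 0.133 for late inflammatory, 0.0503 for nuclear long noncoding and 0.564 for early inflammatory genes. Early inflammatory genes also had 0.0989 without replicate 2 and 0.585 without replicate 3, mitochondrial messenger RNAs 0.0694 and 0.406, and ribosomal protein genes 0.118 without replicate 3, all adjusted permutation p. With all 3 libraries, the early inflammatory genes had an adjusted permutation p of 0.0669 with a pseudocount of 0.1 and of 0.0714 over genes with a mean of 5 TPM or more.

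**Figure D3:**
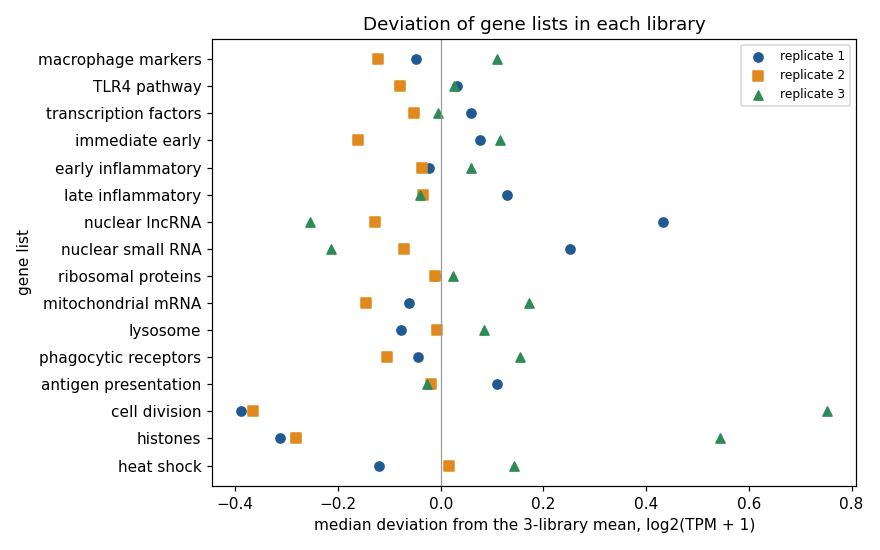
Median deviation of each gene list from its 3-library mean, in log2(TPM + 1), with 1 point per replicate and list. Cell division genes lie at 0.75 in replicate 3 and nuclear long noncoding RNAs at 0.43 in replicate 1, and the ribosomal protein list at -0.01, -0.01 and 0.02 in replicates 1, 2 and 3.

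The 10 genes with the largest spread at a mean of 10 TPM or more were genes of short noncoding RNAs, several with copies at identical values. The small nuclear RNA genes Gm23444 and Gm23472 each read 0, 347 and 364 TPM in replicates 1, 2 and 3, Gm24265 read 0, 358 and 250.5 TPM and Gm24407 0, 195 and 122 TPM. The U3 small nucleolar RNA copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 each read 83.3, 0.01 and 0 TPM, Gm22486, a small nucleolar RNA, 0, 41.1 and 37.1 TPM and the microRNA gene Gm44454 0, 6.04 and 66.6 TPM. Copies with identical values share their reads, so the level of any single copy is uncertain. A TPM of 0 did not always mean that no reads were assigned: Gm24265 had 28, 79 and 35 estimated counts, Gm24407 10, 43 and 17 and Gm22486 2, 7 and 4. In the second quantification, Rnu3b1, Rnu3b2, Rnu3b3, Rnu3b4 and Gm44454 were at 0 TPM in every library.

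Each library had 2 deposited transcript quantifications, and their agreement was compared gene by gene after summing transcripts. Of 6176 genes at 5 TPM or more in either, 49 were at least 2 times higher and 119 at least 2 times lower in the second quantification in all 3 libraries. Without replicate 1, those lower numbered 5914 of 6222. The largest excesses were in pseudogenes and short RNA genes. Gm12896 and Gm12895, processed pseudogenes, differed by a log2 ratio of 20.60 ± 1.08 and 20.60 ± 1.08 (SD, n = 3), and the microRNA genes Gm24245, Gm24270 and Gm23935 each by 19.54 ± 0.22. Mir6236 (11.87 ± 1.16), the small nuclear RNA Gm25047 (9.35 ± 0.22), the mitochondrial transfer RNA mt-Tp (8.95 ± 0.47), Gm19220 (8.46 ± 1.31) and Gm24187 (8.37 ± 0.14) followed. Lower in the second quantification were the pseudogenes Gm10222 (-11.81 ± 0.24), Gm10443 (-10.78 ± 0.18), Gm10925 (-9.69 ± 1.45), Gm14303 (-7.90 ± 2.80) and Gm15899 (-7.89 ± 0.84), the noncoding genes Gm10076 (-9.81 ± 0.54) and Gm26716 (-8.59 ± 0.82), the U3 gene Rnu3a (-8.22 ± 0.61) and the protein-coding entries CAAA01147332.1 (-7.92 ± 0.34) and AC149090.1 (-7.67 ± 0.27). The TPM scale itself differed, since pseudogenes took 14.1%, 43.7% and 54.9% of the second quantification in replicates 1, 2 and 3. Nearly all of this share lay in Gm12895 (67760, 217100 and 273700 TPM) and Gm12896 (67760, 217100 and 273800 TPM). Both had no count in the first quantification, so this share does not describe pseudogenes as a class. The median log2 ratio of all compared genes was -0.46, -1.38 and -1.63 in replicates 1, 2 and 3. After both were rescaled over protein-coding genes, a step chosen after seeing the data, the medians were 0.02, 0.01 and 0.02, with 486 genes higher and 184 lower among 10332.

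Isoform usage of the pathway and response genes was examined last. In 57 genes of the TLR4, transcription factor, immediate early and early inflammatory lists at 5 TPM or more, the leading transcript held over 50% of the gene's TPM in 50 and over 90% in 30, and it was protein-coding in 55. Tlr4-201 held 97.0% ± 0.319 (SD, n = 3) of Tlr4, Myd88-201 99.5% ± 0.263 of Myd88, Cd14-201 86.7% ± 1.19 of Cd14, Fos-201 81.5% ± 8.78 of Fos and Nfkbia-201 98.0% ± 1.01 of Nfkbia. The exceptions were Cd83, led by the retained intron transcript Cd83-202 (71.9% ± 1.66), and Sod2, led by the noncoding transcript Sod2-207 (49.8% ± 2.77). The second quantification named the same leading transcript in 54 of 57 genes and another one in the rest, among them Irf3 and Zfp36.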

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

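Reads assigned to the genome of phiX174, a bacteriophage whose DNA is commonly added to sequencing runs as a control, were present outside the main measurement. They came to 152723 counts in replicate 1, 111164 in replicate 2 and 61136 in replicate 3, far above the 3 counts that a count of 0 allows. These are 0.449%, 0.203% and 0.141% of the counts of the libraries. In a group of 3 samples no single sample was tested for standing apart.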

How the results depend on the processing

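The macrophage list exceeded each of the 8 other cell type lists, and the ribosomal list the nuclear long noncoding list, under all alternatives that gave a value; with members below 1 TPM left out, the T and NK, mast cell and stromal lists had no members. The early inflammatory minus late difference turned to -0.32 under that filter, which removes the 10 low late genes. Lists with a median of 10 TPM or more fell from 12 to 7 in the second quantification, and genes at the detection threshold from 9602 to 5776 at a threshold of 5 TPM, both by construction of a lower scale or a higher threshold. With TPM rescaled over protein-coding genes, a step chosen after seeing the data, 11431 genes reached 1 TPM in every library. In the second quantification rescaled alike, 12322 did. The lowest correlation between libraries was 0.972 for genes with a mean of 1 TPM or more and 0.989 with a pseudocount of 0.1. Shares by estimated counts were 86.7% for protein-coding genes, 8.72% for 7SL, 1.41% for 7SK and 0.858% for RNase P RNA, and in the second quantification 11.4%, 21.5%, 2.92% and 1.98%. With 1 library left out, genes differing beyond counting error ranged from 3514 to 5358, the coefficient of variation from 11.3% to 18.6% (highest without replicate 2) and lists with excess spread from 5 (without replicate 3) to 7, against 9. Excess spread of early inflammatory genes ranged from -0.014 (without replicate 1) to 0.057 with 1 library left out, and the lower spread of ribosomal protein genes became 0.014 on TMM-normalised counts; the cause was not tested. Of the genes compared between quantifications, 255 were higher and 235 lower at 1 TPM, 19 and 65 at 20 TPM, and 486 and 184 after rescaling both over protein-coding genes, a step chosen after seeing the data; those lower ranged from 122 to 5914 with 1 library left out, the highest without replicate 1, whose scale differs least. In the second quantification, the median retained intron share was 11.6% for TLR4 pathway, 11.4% for early inflammatory and 3.06% for antigen presentation genes, against 4.22%, 3.41% and 4.91%. The early inflammatory share was 1.92% without replicate 1. The posterior standard deviation of counts is 0 for many genes, so it was added to the counting variance and not put in its place (6516 differing genes). No paired analysis was possible because the series holds 1 group. Depth limits statements on genes near 0.029 to 0.045 TPM.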

Other observations

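Of the tests in this part, those of library scaling, of marker genes of other bone marrow lineages and of the level of olfactory receptor genes were chosen after the result was seen. For the immediate early genes, the comparison with matched lists was added to the scaling test after its interval was seen, and for the cell division genes the largest rise of a marker took the place of a sum over markers.

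Lysosomal genes were among the highest in these cells. All 18 were above 10 TPM in every library, with a list median of 348 ± 15.3 TPM (SD, n = 3). The highest were Psap and the protease genes Ctsd (4056 ± 314 TPM), Ctsb (2551 ± 182 TPM) and Ctss (931 ± 51.0 TPM). Fc, scavenger and lectin receptor genes had a median of 91.9 ± 10.3 TPM, with Fcer1g at 567 ± 70.6 TPM, Fcgr3 at 223 ± 22.4 TPM and Cd5l at 207 ± 41.4 TPM, while Timd4 was at 0.0133 ± 0.00577 TPM. The scavenger receptor genes Cd36 (74.5, 114 and 234 TPM in replicates 1, 2 and 3) and Marco (0.450, 0.750 and 3.01 TPM) differed several-fold between replicates. Antigen presentation genes had a list median of 27.2 ± 0.972 TPM. The class I chain genes B2m (1728 ± 132 TPM), H2-D1 (1191 ± 67.6 TPM) and H2-K1 (887 ± 72.5 TPM) stood far above it. Of the class II genes, Cd74 was at 108 ± 16.2 TPM, H2-Aa at 40.8 ± 5.01 TPM and their regulator Ciita at 0.787 ± 0.175 TPM. The classes were not compared as sets. Among heat shock genes (median 20.8 ± 2.57 TPM), the constitutive Hspa8 was at 389 ± 30.4 TPM and the inducible Hspa1a and Hspa1b at 0.907 ± 0.175 TPM and 0.317 ± 0.0586 TPM.

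Cell division genes had a median of 2.23 ± 1.76 TPM and histone genes of 12.6 ± 8.21 TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no count in any library, beside Xist at 4.69 ± 3.73 TPM. Of the 13 mitochondrial messenger RNAs (median 301 ± 32.2 TPM), mt-Atp8 (1928 ± 130.2 TPM) and mt-Co1 (1221 ± 118 TPM) were highest and mt-Co2 was lowest at 0, 9.08 and 29.3 TPM. The short mt-Atp8 had only 1611, 4026 and 2953 estimated counts, against 105719, 149126 and 133581 for mt-Co1. In the second quantification mt-Atp8 (464.3, 323.2 and 266.2 TPM) lay below mt-Co1 (862.5, 419.0 and 435.1 TPM), so their order is uncertain. The nuclear copies of mitochondrial genes on chromosome 1, Gm28661 (1173 ± 143 TPM), Gm28437 (825 ± 143 TPM) and Gm10925 (648 ± 98.4 TPM), can share reads with the mitochondrial genes, so these levels are uncertain. The cytosolic small RNA list had a median of 67.7 ± 17.4 TPM, the ribosomal RNA list of 4.03 ± 1.14 TPM and the nuclear long noncoding list of 1.11 ± 0.338 TPM.

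All 18 cell division genes and all 19 histone genes were highest in replicate 3. Library scaling was argued against: on TMM-scaled CPM the median log2 ratio of the cell division genes in replicate 3 over the other libraries was 1.54 (95% bootstrap interval over genes 1.26 to 1.72), with 18 of 18 genes above 0. GC content was argued against, since that median lay at percentile 100.0 of 10000 lists matched on GC content and expression, whose highest median was 0.25. Immature bone marrow cells of other lineages in the culture were not excluded: the largest TPM rise among 38 markers of neutrophils, mast cells, erythroid cells and B cells was 2.13, for S100a9, within the interval of the cell division genes' median rise (1.93 to 3.95). S100a9 was higher in replicate 2 than in replicate 3 (13.1, 20.8 and 19.1 TPM in replicates 1, 2 and 3), unlike the cell division genes. The precursor markers Mpo, Elane, Prtn3, Klf1, Cd79a and Kit differed by only 0.175, 0.06, -0.16, 0.045, -0.025 and 0.08 TPM against a median rise of 2.81 for the cell division genes. Other neutrophil markers went both ways. Ngp (1.84, 2.89 and 3.18 TPM) and Mmp8 (6.06, 5.06 and 6.93 TPM) were highest in replicate 3, while Ltf (0.560, 0.660 and 0.530 TPM) and Prtn3 (0.680, 0.880 and 0.620 TPM) were lowest there. These markers do not settle whether such cells were more frequent in replicate 3. Osteoclast markers other than Calcr, at 0 TPM in each library, were also highest in replicate 3 and were not among the 38, with Atp6v0d2 at 49.2, 48.9 and 75.5 TPM, Ctsk at 0.860, 0.790 and 1.70 TPM and Dcstamp at 0.160, 0.06 and 0.540 TPM in replicates 1, 2 and 3. A larger share of dividing macrophages in replicate 3 may also account for it, which the design does not test.

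The 6 detected nuclear long noncoding RNAs were highest in replicate 1. Scaling was argued against by a median log2 ratio of 0.85 (95% bootstrap interval over genes 0.38 to 2.45) on TMM-scaled CPM, in 6 of 6 genes. Genomic DNA was tested with olfactory receptor genes, whose summed CPM was 1.58 times that of the next library, past the ratio of 1.5 set beforehand as a sign of it. Of these counts, 51.6% lay in Olfr111 and Olfr56. In the later test, which argues against genomic DNA as the source of the whole excess, the mean TPM rise over 1093 olfactory receptor genes was 0.00164 against a lowest rise of 0.22 among the nuclear RNAs. Carry-over of nuclear RNA into the cytosolic fraction was weighed with the retained intron share and with nuclear small RNAs. The median rise of the retained intron share in replicate 1 was 0.715 percentage points (95% bootstrap interval over genes 0.665 to 0.762). The share was higher there in 2954 of 3870 genes. That median is past the 0.2 percentage points set beforehand as a sign of carry-over. The interval does not measure the spread between libraries, and replicates 2 and 3 also differed, with median shares of 1.35% and 1.05%. The nuclear small RNA list had its highest median deviation in replicate 1 on the deposited TPM (0.25, -0.07 and -0.21). The same held on TPM rescaled over protein-coding genes (0.29, -0.03 and -0.30), a step chosen after seeing the data. On TMM-scaled CPM it was highest in replicate 2 (0.01, 0.12 and -0.19). The 7SK RNA was likewise highest in replicate 1 as a share of TPM (7.93%, 7.77% and 5.61%) and in replicate 2 as a share of counts (1.41%, 1.72% and 1.09%). The cytosolic 7SL RNA was also highest in replicate 2 as a share of counts (7.37%, 10.0% and 8.77%), so count shares of short RNAs cannot decide the question. Carry-over stays open. No biological explanation was tested.

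Immediate early genes, among them Fos, Junb and Ier3, had their lowest value in replicate 2 in 12 of 21 cases. On TMM-scaled CPM the median log2 ratio in replicate 2 was -0.21 (95% bootstrap interval over genes -0.51 to -0.06), with 15 of 21 genes below 0. It lay at percentile 0 of 10000 lists matched on GC content and expression, whose lowest median was -0.08, which argues against GC content and against a scaling that would move matched genes alike. A small difference in the time or strength of stimulation, or in handling, may account for it and stays untested, since the labels give 10 minutes and 100 ng/ml for all 3 libraries.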
